A study of Homo sapiens with 4 samples.

How the data were processed

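Gene expression was measured by poly(A) RNA sequencing in 4 libraries of MOLM13 cells, a line established from a human acute myeloid leukaemia, in a subline the labels call resistant to venetoclax, an inhibitor of BCL2. Per the labels, doxycycline induced a short hairpin RNA (shRNA) in every library. A control hairpin was induced in 2 libraries and a hairpin against PRMT9, a protein arginine methyltransferase, in the other 2. Per the labels' protocols, RNA was extracted with Trizol, each sample had an RNA integrity number above 8, and libraries were made with a Kapa mRNA HyperPrep kit and sequenced on a NovaSeq X. The labels number the libraries 1 and 2 within each group, without saying whether the numbers stand for separate cultures, for technical repeats of 1 culture or for different hairpin sequences. P-values here therefore measure only the spread between these libraries, and so do the SDs and the coefficient of variation.

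The authors deposited raw read counts per Ensembl gene for the 4 libraries, and RPKM values of the same genes, with gene coordinates on GRCh38. Trimmomatic 0.39, STAR 2.7.2a and SAMtools 1.10 are named in the submitters' processing notes without their roles. The counting program, its handling of reads that map to several places, its use of strand and the annotation release are not given in the sources used here. In each library the authors' deposited RPKM equalled the count divided by exon length and by the library total times 1 factor (1.01, 0.979, 1.01 and 1.00), and these factors were the ones that TMM scaling gave on all 57992 rows. Of these rows, 57388 have a gene identifier in GENCODE release 29, and 55306 have the same start and end there. Gene symbols are those of the count table, with the current symbol added where it differs.

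The total count per library ranged from 28592902 to 33845172. Genes with too few reads were removed with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 15193 genes holding 99.9% of the counts. The main test was edgeR's quasi-likelihood test with TMM scaling, a group term and robust empirical Bayes estimation, in R 4.3.3. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, with no limit on the fold. Log2 fold changes are PRMT9 hairpin over control hairpin. CPM values are scaled by the TMM factors, and means are given ± SD over the 2 libraries of a group. In simulated counts for this comparison on 15193 genes, with the real means and library sizes and 50 genes changed at each of 4 folds, the test called 23 genes changed by 1.25-fold, 31 changed by 1.5-fold, 38 changed by 2-fold and 45 changed by 4-fold, all in the right direction. It also called 6 of 14993 unchanged genes. The share of changed genes was far smaller in the simulation than among the real calls, so these counts do not give the sensitivity of the test on the data. In the same simulation a list of 50 genes shifted by 1.25-fold was called, and 0 of 36 unshifted lists were, with genes drawn independently of each other.

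Before the data were examined, 38 gene lists with 1174 entries were fixed (splicing and translation, interferon and innate sensing, apoptosis, cell cycle and DNA repair, metabolism, stress responses, myeloid identity and markers of other cell types), along with the alternatives and the rule for naming genes. Lists with at least 5 tested members, 36 in all, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. The test was repeated with an estimated correlation, which with 4 libraries rests on 2 residual degrees of freedom, and with fry, which tests a list by itself. Genes are named by these rules: PRMT9, the 10 largest rises and 10 largest falls among genes past the threshold that are not pseudogenes, antisense or non-coding genes, at a mean of 10 CPM or more with both groups apart, up to 3 called members with the lowest adjusted p of each list closest to the question (such as splicing, translation, interferon, apoptosis, DNA repair, respiration and myeloid identity), up to 2 of each other list called by camera and 1 of each list not called, every tested member of the anti-apoptotic BCL2 family, and the published PRMT9 substrates SF3B2 and PABPC1. This gave 102 genes, some of which are not reported here. Other members, named as the few exceptions within a list, were chosen after their values were seen.

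The alternatives comprised other scalings, filters on low counts, DESeq2 1.42.0, limma-voom, earlier or less robust edgeR settings, a test against a fold of 1.5, an adjusted p below 0.01, the deposited RPKM in limma on log2(RPKM + 1) and log2(RPKM + 0.1) above a filter on low values and without one, the replicate number as a block, each library left out in turn, camera by ranks, and fry. Offsets for GC content and exon length, and a fit without mitochondrial genes, were added after the data were seen. Reads shared between genes were examined in GENCODE release 29 for the 102 named genes. Exons of another gene on the opposite strand cover at least 20% of the exon bases of ACTA2, BCL2L1, DDIT4, DUSP6, LYZ, PKMYT1 and TYMS. At least 10% of the 50-base windows of BCL2L2, EIF5A, FCGR2A, HIST1H2BK, HMGB1, MT-CO3, MT-ND2, RPL12, UQCRFS1 and WDR77 also occur in transcripts of another gene. Values of these 17 genes are uncertain to that extent. Splicing and translation themselves cannot be read from counts per gene and were not analysed here.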

Results

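Messenger RNA was profiled in MOLM13 cells, an established line of human acute myeloid leukaemia that carries a KMT2A fusion, in a venetoclax-resistant derivative. Doxycycline induced a control hairpin in 2 libraries and a hairpin against PRMT9 in 2 libraries. PRMT9 is a protein arginine methyltransferase whose known substrates include the splicing factor SF3B2. Total counts were 30329901 and 28592902 in the control libraries and 30764403 and 33845172 in the PRMT9 hairpin libraries. Between 22966 and 24585 genes had a count in a library. Mitochondrial genes took 7.40% and 7.28% of the counts in the controls and 6.97% and 7.06% after PRMT9 knockdown. The most abundant gene in each library was EEF1A1, with 2.17% and 2.22% of the counts in the controls and 2.85% in each knockdown library. The correlation of log2 CPM across genes was 0.993 between the control libraries and 0.995 between the knockdown libraries, against 0.966 to 0.968 between groups.

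PRMT9 RNA was 5.59-fold lower in the knockdown libraries than in the controls. The gene (ENSG00000164169, chromosome 4, 147637785 to 147684230 on the minus strand of GRCh38) had 398 and 406 counts in the control libraries and 81 and 78 counts in the knockdown libraries. This corresponds to 13.7 ± 0.823 CPM (SD, n = 2 libraries) in the controls and 2.46 ± 0.227 CPM (SD, n = 2 libraries) after knockdown. In the authors' RPKM the means were 3.42 ± 0.264 and 0.611 ± 0.0555. The log2 fold change was -2.48 (SE 0.12, edgeR adjusted p = 1.13e-11), and 17.9% of the control level remained (95% confidence interval 15% to 21.4%). In log2(RPKM + 1) the change was -1.46.

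**Figure D1:**
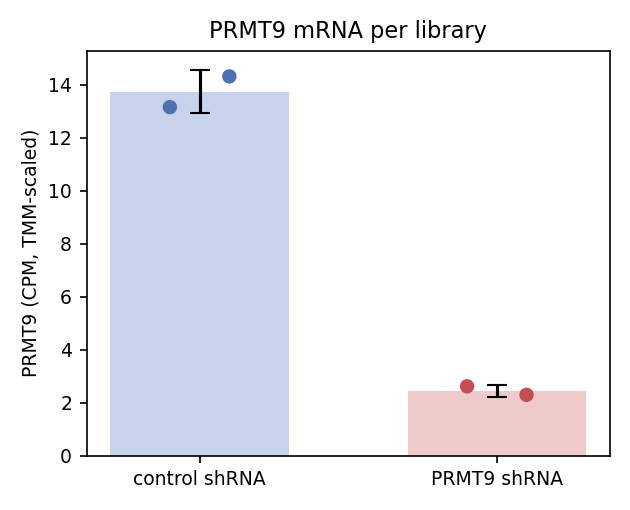
PRMT9 expression in CPM in each library, with the group mean and SD (2 libraries per group). The knockdown libraries lie at 2.62 and 2.30 CPM, below the control libraries at 13.2 and 14.3 CPM.

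The main comparison asked which transcripts differ when PRMT9 is depleted in venetoclax-resistant cells. Most of the measured transcriptome differed, with many small changes, and the strongest rises included interferon-induced and histone genes while the strongest falls included a cystine transporter gene. Of 15193 genes tested, 10327 changed (68.0%), of which 5078 rose and 5249 fell. The median size of a change was 0.52 on the log2 scale, and 2085 genes changed by 2-fold or more, 1514 of them upwards and 571 downwards. The balance of rises and falls, and the direction of small changes, depend on the scaling. With upper-quartile scaling 5933 genes rose and 4443 fell. The coefficient of variation between libraries of a group, beyond counting error, was 0.0259, and the labels leave open whether they are separate cultures or technical repeats. In 83.3% of tested genes both libraries of one group lay beyond both of the other, against 33.3% by chance. This held for 10326 of the changed genes, which a call with 2 libraries per group nearly requires.

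The largest rise among the protein-coding genes named by rule was in OAS2, an interferon-induced sensor of double-stranded RNA (chromosome 12, 112978395 to 113011723). OAS2 went from 6.60 to 118 CPM, a log2 fold change of 4.17 (SE 0.05, adjusted p = 1.89e-18). The interferon-induced genes IFIT1 and IFIT2 rose by 3.78 and 3.34. SPP1, which encodes osteopontin, rose by 3.44. The histone genes HIST1H2AC (H2AC6) and HIST1H2BD (H2BC5) rose by 3.92 and 3.49. The other large rises were in the creatine kinase gene CKB (3.42), the aminotransferase gene AGXT (3.41) and the creatine transporter gene SLC6A8, which went from 25.9 to 251 CPM (3.28, adjusted p = 7.51e-20).

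The largest fall among the genes named by rule was in SLC7A11, the cystine-glutamate exchanger that supplies cysteine for glutathione (chromosome 4, 138164097 to 138242349). SLC7A11 went from 34.7 to 5.29 CPM, a log2 fold change of -2.71 (SE 0.08, adjusted p = 1.22e-14). HMGB1, an abundant chromatin protein gene, went from 1110 to 304 CPM (-1.87, adjusted p = 7.51e-20), and 10.7% of its 50-base windows also occur in other genes. The 10 largest falls also included genes of DNA replication and cell cycle control, namely E2F2 (-1.91), GINS2 (-1.83), MCM10 (-1.80) and PKMYT1 (-1.73), a kinase that restrains entry into mitosis. VAT1L fell from 199 to 52.7 CPM, VKORC1L1 from 94.8 to 27.4 CPM, GPR180 from 29.1 to 6.85 CPM and SHISA2 from 23.9 to 6.88 CPM. The 3' UTRs of GPR180, HMGB1, GINS2 and VKORC1L1 hold a 7-base sequence whose carriers were lower as a set (described among the other observations), as do those of EIF3B, GSPT1, IARS, MCL1, BMF, MKI67, MRPS16 and WDR77.

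**Figure D2:**
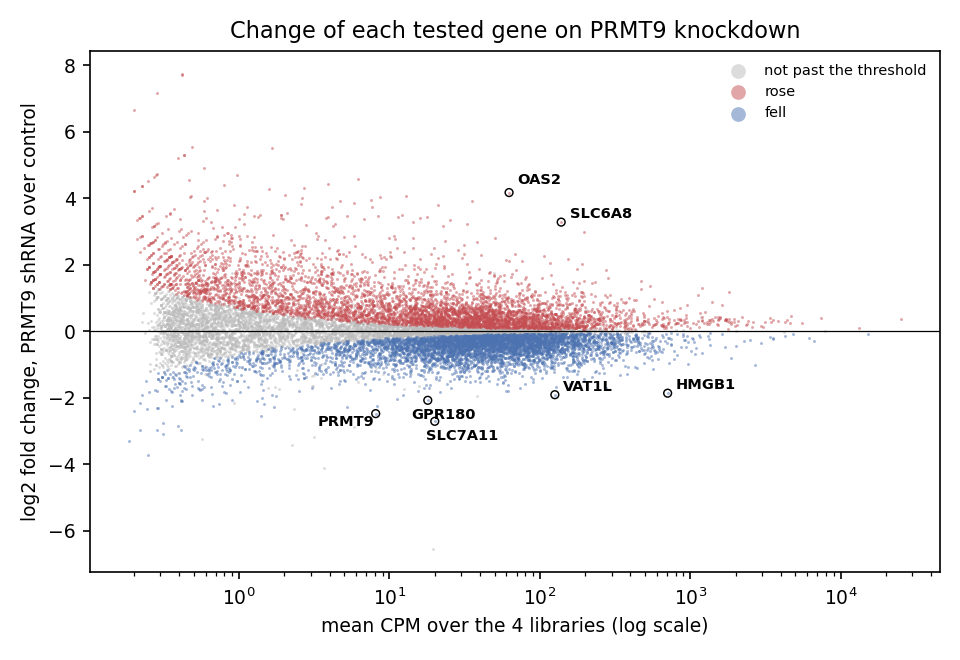
Log2 fold change (PRMT9 hairpin over control hairpin) of each of the 15193 tested genes against its mean expression in CPM on a log axis, with called genes coloured and some named genes circled. OAS2 lies at 4.17 and SLC7A11 at -2.71.

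Among 38 gene lists fixed before the data were examined, 36 could be tested, of which 9 were called higher and 15 lower in the knockdown libraries relative to other genes. None of these 24 calls held at an adjusted p below 0.05 when the correlation between genes was estimated from the 4 libraries, where the lowest adjusted p was 0.138. That test rests on 2 residual degrees of freedom and has little power. The estimated correlation was -0.017 for interferon-stimulated genes and for G1/S genes, below the preset 0.01. For these lists the lost call therefore does not come from a higher correlation between genes. In log2(RPKM + 1), where the added 1 shrinks changes of weakly expressed genes, the median log2 fold change was 0.78 for histones, 0.60 for epithelial and stromal markers and 0.34 for nucleic acid sensing, against 2.01, 1.01 and 0.59 in the main test. Without a filter on low values it was 0.38, 0.02 and 0.10 for these lists, 0.49 for NF-kB genes, 0.27 for monocyte markers and 0.13 for MHC class II. Counts of members adjusted over the list alone are given below where they differ from those over all genes, which was so in 5 lists, and in the other 33 they were the same. Members named because they stood apart from the rest of a list were chosen after their values were seen unless the naming rule had also picked them.

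Interferon-stimulated genes rose almost as a block. All 50 type I interferon-stimulated genes were tested, 48 rose and 2 fell, with a median log2 fold change of 1.35 (camera adjusted p = 2.20e-13; adjusted p = 0.138 with an estimated correlation). SAMD9L, an antiviral restriction factor, rose by 2.09, and STAT2, a transcription factor of the interferon response, went from 51.3 to 156 CPM (1.61). The 2 members that fell, PARP12 (-0.28) and the RNA editing enzyme gene ADAR (-0.20), stood apart. Of 18 tested genes on the list of cytosolic nucleic acid sensing, 12 rose and 5 fell, with a median of 0.59 (adjusted p = 0.0430; adjusted p = 0.336 with an estimated correlation). As fixed, that list also holds Toll-like receptor and nuclease genes, so it is wider than the cytosolic sensors. The DNA sensor gene IFI16 rose by 1.46, TMEM173 (STING1) by 0.60 and SAMHD1, which encodes a nucleotide hydrolase, by 0.45. The falls were in the DNA sensor gene MB21D1 (CGAS), the kinase gene TBK1 and the RNase H2 subunit genes RNASEH2A, RNASEH2B and RNASEH2C. The call on this list was lost without PRMT9 shRNA replicate 1 (median 0.49, adjusted p = 0.0590) and without PRMT9 shRNA replicate 2 (median 0.62, adjusted p = 0.0524). It was also lost with upper-quartile scaling (median 0.68, adjusted p = 0.0748), a filter at 1 CPM (0.48, adjusted p = 0.109), log2(RPKM + 1) (0.34, adjusted p = 0.116), log2(RPKM + 0.1) (0.35, adjusted p = 0.123) and the GC and length offsets added after the data were seen (0.55, adjusted p = 0.0524).

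Inflammatory genes and MHC class II genes were also called higher. Of 25 tested NF-kB and inflammatory cytokine genes, 21 rose and 2 fell (median 0.89, adjusted p = 1.12e-05; adjusted p = 0.147 with an estimated correlation). CCL4 had no count in the controls. Its lower bound of 16.3-fold lies above the list median, so setting it there left the median at 0.89 by construction. The falls were in NFKB1 and SOD2. NFKB2, an NF-kB subunit gene, went from 8.84 to 53.7 CPM (2.60), and TNFAIP3, an inhibitor of NF-kB signalling, from 46.5 to 120.7 CPM (1.38). MHC class II genes had 5 rises and no fall among 8 tested members (median 0.55, adjusted p = 0.0149; adjusted p = 0.226 with an estimated correlation), a call lost with DESeq2 (median 0.64, adjusted p = 0.114). The rises were in the invariant chain gene CD74 (0.78), HLA-DMA (0.92), HLA-DMB, HLA-DRA and CIITA. In the MHC class I list 12 of 17 members rose and 4 fell (median 0.33), which was not called (adjusted p = 0.0504). HLA-E rose from 152.7 to 316 CPM (1.05), and the falls were in TAP2, NLRC5, ERAP1 and PSME2. That list passed the threshold without control shRNA replicate 1 (median 0.30, adjusted p = 0.0400) and without control shRNA replicate 2 (median 0.36, adjusted p = 0.0320).

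Markers of other cell types were examined beside these groups. Of 22 epithelial and stromal markers 7 were tested, of which 6 rose and 0 fell (median 1.01, adjusted p = 0.00585; adjusted p = 0.292 with an estimated correlation). Of these, PECAM1, an adhesion molecule that myeloid cells also carry, went from 140.8 to 241.7 CPM and the actin gene ACTA2 from 21.4 to 43.9 CPM. The keratin gene KRT8, chosen after its value was seen, went from 5.20 to 10.9 CPM. Of 25 lymphoid markers 7 were tested, 3 rose and 2 fell, and the list was not called (adjusted p = 0.524). Its median was -0.09, its mean 0.69 and the direction of the test upwards, and IL7R rose by 1.11. The other rises were in IGKC and NKG7, and the falls in PAX5 and NCAM1. Of 22 erythroid and megakaryocyte markers only 3 were tested, 2 of which rose, EPOR (0.42) and ITGA2B, and the list was too small to test.

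Proliferation genes fell together. Of 46 genes of G1/S and DNA replication, 45 fell and 0 rose, with a median log2 fold change of -0.99 (adjusted p = 2.17e-14; adjusted p = 0.138 with an estimated correlation). The replicative helicase gene MCM3 fell by 1.26, and the thymidylate synthase gene TYMS went from 250.1 to 107.7 CPM. The member that did not pass was CDT1 (-0.01, adjusted p = 0.869). Of 51 genes of G2/M and mitosis, 50 fell and 0 rose, or 1 rose adjusted over the list alone (median -0.66, adjusted p = 2.01e-13; adjusted p = 0.197 with an estimated correlation). The proliferation marker MKI67 went from 952 to 484 CPM (-0.97), and CENPF, a kinetochore gene, from 494 to 239.7 CPM (-1.04). The member that rose over the list alone was CDC25C (0.19, adjusted p = 0.0512 over all genes).

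Genes of homologous recombination, the Fanconi pathway and replication stress fell as well. Of 49 tested members 42 fell and 4 rose (median -0.67, adjusted p = 1.90e-08; adjusted p = 0.138 with an estimated correlation). CLSPN, an adaptor of the replication checkpoint, fell by 1.62, the exonuclease gene EXO1 by 1.54 and the helicase gene BLM by 1.09. The members that rose were RAD50, ATM, CHEK2 and FANCF. Replication-dependent histone genes moved the other way. Of 19 tested histone genes 14 rose and 1 fell, with a median of 2.01 (adjusted p = 8.27e-05; adjusted p = 0.165 with an estimated correlation). HIST1H2BK (H2BC12) went from 8.96 to 48.2 CPM (2.43), although 74.1% of its 50-base windows also occur in other genes. The histone gene that fell was HIST1H1E (-1.34).

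**Figure D3:**
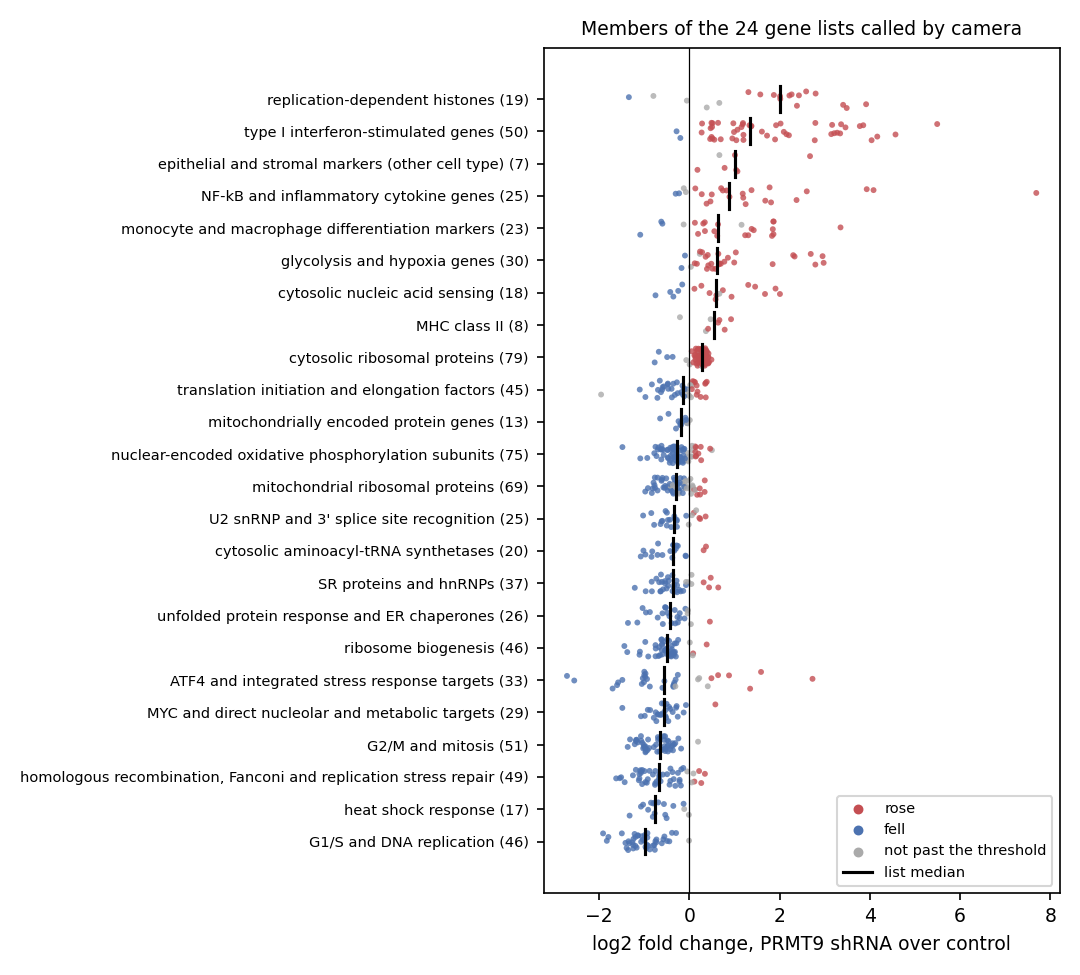
Log2 fold change (PRMT9 hairpin over control hairpin) of the tested members of the 24 called lists, with 1 point per gene, coloured by call, and a line at each list's median. The point at 7.69 is CCL4, which had no control count, so that its fitted value is no bound, and the median was 1.35 for interferon-stimulated genes, 2.01 for histones and -0.99 for G1/S and DNA replication.

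The series title names splicing and translation, and the RNA levels of the factors behind both were examined. Splicing factor transcripts were lower by a modest amount. Of 25 members of the U2 snRNP and 3' splice site list 18 fell and 4 rose (median -0.33, adjusted p = 0.00306; adjusted p = 0.197 with an estimated correlation). The helicase genes DDX46 and DHX15 fell by 1.03 and 0.60, whereas SF3B1 rose by 0.36. The other rises were in SF3A2, SF3B6 and SUGP1. RNA of SF3B2 itself fell by 0.32 (SE 0.02, adjusted p = 3.16e-09; chromosome 11, 66050729 to 66069308). Of 37 SR protein and hnRNP genes 29 fell, or 30 adjusted over the list alone, and 4 rose (median -0.37, adjusted p = 1.78e-05; adjusted p = 0.226 with an estimated correlation). With the GC and length offsets the median was -0.24. HNRNPAB, HNRNPR and HNRNPF fell by 1.21, 0.97 and 0.84. The 4 that rose were the splicing factor SRSF5 and the kinases of SR proteins CLK1, CLK3 and CLK4. Nonsense-mediated decay factors and reporters included 13 falls and 4 rises among 21 genes (median -0.20) and were not called (adjusted p = 0.0849). SMG5, a decay factor, fell by 0.63, and the rises were in UPF2, SMG6, GAS5 and SNHG8.

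Transcripts of the translation machinery split by class. Cytosolic ribosomal protein genes were higher, with 71 of 79 rising and 4 falling (median 0.28, adjusted p = 3.23e-09; adjusted p = 0.343 with an estimated correlation). RPL28 rose by 0.49, and RPL12 and RPLP1 by 0.42 each. Ribosome biogenesis genes were lower, with 42 of 46 falling and 2 rising (median -0.50, adjusted p = 1.58e-09; adjusted p = 0.138 with an estimated correlation). The helicase gene DDX21 fell by 0.98 and UTP20, which acts in processing of small subunit RNA, by 1.38, while FBL and NOB1 rose. Of 20 cytosolic aminoacyl-tRNA synthetase genes 18 fell and 2 rose (median -0.37, adjusted p = 8.27e-05; adjusted p = 0.292 with an estimated correlation), with IARS (IARS1, -1.08) and MARS (MARS1, -1.02) among the falls and DARS and QARS as the rises. Translation initiation and elongation factors had 26 falls and 12 rises among 45 tested members (median -0.15, adjusted p = 0.0263; adjusted p = 0.383 with an estimated correlation). This call was lost with upper-quartile scaling (median -0.06, adjusted p = 0.0748), with a filter at 1 CPM (-0.12, adjusted p = 0.0735), in log2(RPKM + 0.1) (-0.15, adjusted p = 0.0503) and with GC and length offsets chosen after seeing the data (-0.15, adjusted p = 0.0568). The initiation factor gene EIF3B went from 358 to 167 CPM, and the release factor gene GSPT1 fell by 0.83 and EIF5A by 0.60. PABPC1, which encodes a poly(A)-binding protein, fell by 0.15 (SE 0.01, adjusted p = 1.29e-07).

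Stress response genes were mostly lower. Of 33 tested ATF4 and integrated stress response targets 23 fell and 6 rose (median -0.55, adjusted p = 0.00210; adjusted p = 0.192 with an estimated correlation). The serine synthesis gene PSAT1 went from 237 to 78.1 CPM, and the amino acid transporter gene SLC7A5 fell by 1.03. In contrast DDIT4, an inhibitor of mTORC1, went from 307 to 780 CPM (1.35). The other rises were in the stress-induced genes NUPR1 (2.73), PPP1R15A (1.59), which encodes a phosphatase subunit that reverses the block on translation, DDIT3 (0.88) and ATF5 (0.64), and in the folate enzyme gene MTHFD2 (0.49), all chosen after their values were seen. Of 26 genes of the unfolded protein response 22 fell and 1 rose (median -0.42, adjusted p = 1.64e-05; adjusted p = 0.147 with an estimated correlation). The endoplasmic reticulum chaperone genes HYOU1 and HSPA5 fell by 1.04 and 0.70, and the rise was in EDEM1. Heat shock genes had 15 falls and 0 rises among 17 tested members (median -0.77, adjusted p = 4.60e-06; adjusted p = 0.196 with an estimated correlation). HSPA8 went from 3606 to 1770 CPM (-1.03), and HSPH1 fell by 1.33. Of 29 tested members of the list of MYC and its targets 28 fell and 1 rose (median -0.57, adjusted p = 1.57e-07; adjusted p = 0.138 with an estimated correlation). The polyamine synthesis gene ODC1 fell by 0.99 and the transferrin receptor gene TFRC by 0.79, while LDHA, a gene of glycolysis, rose by 0.58.

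BCL2, the target of venetoclax, fell by about a factor of 2 in RNA level, while other members of its family moved in different directions. BCL2 (chromosome 18, 63123346 to 63320128) went from 95.4 to 47.4 CPM, a log2 fold change of -1.01 (SE 0.04, adjusted p = 7.19e-13). MCL1 and BCL2L1, which also block apoptosis, fell by 0.20 (adjusted p = 2.83e-07) and 0.38 (adjusted p = 2.84e-04). BCL2A1 rose from 0.785 to 4.16 CPM (2.40, SE 0.21, adjusted p = 2.52e-08), a low level next to BCL2. BCL2L2 did not pass the test (0.06, adjusted p = 0.526). The list of 5 tested anti-apoptotic members was not called (adjusted p = 0.477), and its median was -0.20 while its mean was 0.17. Pro-apoptotic members and effectors included 9 rises and 9 falls among 20 genes and were not called either (adjusted p = 0.865). Their median was -0.02 and their mean -0.01 with an upward direction of the test, and the median was between -0.02 and 0.07 over the scalings tried. BMF, a BH3-only gene, rose by 1.44 and the mitophagy receptor gene BNIP3L by 0.94, and the cytochrome c gene CYCS fell by 1.22. Of 35 tested p53 targets 19 rose, or 20 adjusted over the list alone, and 12 fell (median 0.21), without a call (adjusted p = 0.107). BTG2, an antiproliferative gene, rose by 1.64. Of 9 drug efflux and venetoclax metabolism genes only 4 were tested, too few for a test of the list. MVP (1.06) and ABCC1 rose, joined by ABCC2 when adjusted over the list alone (3 rises rather than 2), and ABCC4 fell by 0.82.

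**Figure D4:**
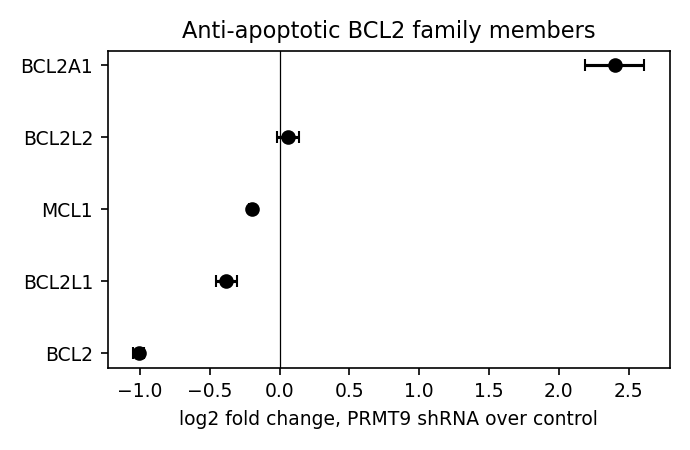
Log2 fold change (PRMT9 hairpin over control hairpin) of the 5 tested anti-apoptotic BCL2 family genes, with SE bars. BCL2 lies at -1.01 and BCL2A1 at 2.4.

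Mitochondrial transcripts were modestly lower. Of 75 nuclear-encoded oxidative phosphorylation subunits 55 fell and 9 rose, or 10 adjusted over the list alone (median -0.27, adjusted p = 1.64e-05; adjusted p = 0.138 with an estimated correlation). The complex I genes NDUFS6 and NDUFS1 fell by 1.49 and 0.75, and the complex III gene UQCRFS1 by 0.62. Of 13 mitochondrially encoded protein genes 11 fell and 0 rose (median -0.18, adjusted p = 0.0171; adjusted p = 0.441 with an estimated correlation), with MT-CO3 at -0.30 and MT-ND2 at -0.24. This call was lost with upper-quartile scaling (median -0.10, adjusted p = 0.110) and with a filter at 1 CPM (median -0.15, adjusted p = 0.0528). Mitochondrial ribosomal protein genes had 45 falls and 6 rises among 69 members (median -0.30, adjusted p = 1.03e-05; adjusted p = 0.138 with an estimated correlation). MRPL20 fell by 0.92 and MRPS16 by 0.77. Glycolysis and hypoxia genes were higher, with 26 of 30 rising and 2 falling (median 0.61, adjusted p = 8.79e-08; adjusted p = 0.226 with an estimated correlation). NDRG1, a gene induced by low oxygen, went from 44.3 to 349 CPM (2.98), and P4HA1, a subunit of collagen prolyl hydroxylase, from 119 to 428 CPM (1.85), while PFKL and PGAM1 fell. Cholesterol biosynthesis genes had 14 rises and 6 falls among 24 genes (median 0.18) and were not called (adjusted p = 0.0586).

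Markers of monocytes and macrophages were higher in the knockdown libraries. Of 23 tested members 18 rose and 3 fell (median 0.63, adjusted p = 2.19e-04; adjusted p = 0.165 with an estimated correlation). The integrin gene ITGAM (CD11b) went from 30.6 to 108.8 CPM (1.83), the Fc receptor gene FCGR2A from 66.0 to 177 CPM (1.43) and the lysozyme gene LYZ from 607 to 942.5 CPM (0.63). The falls were in FCGR1A, MNDA and CEBPB. Granule and promyelocyte genes had 9 rises and 6 falls among 16 genes (median 0.12, adjusted p = 0.426), with the granule protein gene AZU1 at 0.70. HOXA, MEIS1 and other KMT2A fusion targets had 12 rises and 9 falls among 25 genes (median 0.14, adjusted p = 0.373). LMO2 rose by 0.97 and JMJD1C by 0.39, and CDK6 fell by 0.39. Neither list was called.

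Of 9 tested genes for other arginine methyltransferases and their cofactors 7 fell and 2 rose (median -0.24), without a call (adjusted p = 0.0744). PRMT2 rose from 27.5 to 77.1 CPM (1.49) and PRMT7 by 0.12, while PRMT3 fell by 0.86 and WDR77, the partner of PRMT5, by 1.09. MAPK feedback genes had 7 rises and 3 falls among 15 genes (median 0.04, adjusted p = 0.477), with the phosphatase gene DUSP6 at 0.55 and falls in SPRY4, SPRED1 and ETV4. Immediate-early genes had 12 rises and 4 falls among 23 genes (median 0.31, adjusted p = 0.0890). BTG2 was among the rises, and the falls were in MYC, DUSP1, SRF and MCL1. Neither of these lists was called.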

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

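Among 24 alternatives, of which the GC and length offsets and the fit without mitochondrial genes were chosen after seeing the data, those that refitted the genes called between 7835 and 10376 changed, except that the test against a fold of 1.5 called 2884 (1679 rose, 1205 fell), fewer by its own construction. DESeq2 called 7941. Leaving out 1 library gave 9301 to 9889 changed genes (4496 to 4898 rose, 4804 to 5048 fell), 23 to 25 lists called (8 to 10 higher, 15 to 15 lower) and a PRMT9 log2 fold change of -2.58 to -2.39, with the lone library assumed to vary like the others. Over all settings PRMT9 lay between -2.58 and -1.46, the last in log2(RPKM + 1), where the added 1 exceeds its RPKM after knockdown, and it was called each time. With an estimated correlation, a test on 2 residual degrees of freedom, 0 lists were called (0 higher, 0 lower). Fry called 36 lists, 19 higher, and gave the anti-apoptotic BCL2 list an upward direction (adjusted p = 0.00895) against its median of -0.20; the median and mean of these 5 genes differ in sign. Outside these 2 tests 4 lists lost a call under some setting, namely nucleic acid sensing (8 settings), translation factors (5), mitochondrially encoded genes (3) and MHC class II (2). A call was gained by 6 lists, MHC class I (9), cholesterol biosynthesis (7), immediate-early genes (4), nonsense-mediated decay (2), other methyltransferases (2) and p53 targets (1), and the cause was not tested. Of the values of named genes 2116 stayed on their side of the threshold and, where called, kept their direction. Direction was not compared where a gene passed in neither test. Another 24 kept the direction alone, 21 of them in the test against 1.5-fold. The other 3 were MT-CO3, MT-ND2 and PABPC1 in unfiltered RPKM. In 2 cases a named gene had no value. Upper-quartile scaling moved the median of all genes by 0.09, and 57.2% of its changed genes rose. After GC and length correction 9647 of the changed genes were called in both, and 17 had the opposite direction. No pairing of the libraries by the numbers 1 and 2 was seen. The deviations of like-numbered libraries correlated at -0.03 across 15193 genes, and at -0.04 across 9052 genes with a mean of 10 CPM or more. Counting error enters these deviations, so a pairing is not excluded. With the number as a block 10307 genes changed. At this depth the self-test called 62% of genes changed by 1.5-fold, with 14993 of its 15193 genes unchanged. In the data 68.0% of genes were called, which makes the adjusted threshold less strict. The self-test therefore does not give the share missed here, although changes of that size can be missed. Camera does not use the edgeR fit, so 3 settings of that fit gave no list values.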

Other observations

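Several further gene groups, put together after the data were seen, were called as sets, each tested with camera and adjusted over the 8 added lists, and each with an adjusted p of 0.130 with an estimated correlation. Proteasome subunit genes were lower, with 29 of 31 falling and 1 rising (median log2 fold change -0.56, adjusted p = 2.70e-08), among them PSMD1 (-1.24) and PSMD11 (-1.07). Genes of the nuclear pore and nuclear transport fell in 29 of 30 cases (median -0.52, adjusted p = 2.54e-08), with the importin gene KPNA2 at -1.20. Of 15 genes of the Sm and LSm core of spliceosomal particles 14 fell (median -0.55, adjusted p = 1.14e-04), with SNRPG at -0.98. Serine, glycine and one-carbon metabolism genes fell in 19 of 21 cases (median -0.49, adjusted p = 1.20e-05), PHGDH by 0.94. Genes for subunits of the chaperonin CCT and of its partner prefoldin fell in 10 of 14 cases and rose in 3 (median -0.35, adjusted p = 0.0123), with the CCT subunit gene CCT6A at -1.30. Lysosomal genes were higher, with 17 of 27 rising and 6 falling (median 0.39, adjusted p = 0.00782), among them the hydrolase genes GAA (0.99) and CTSB (0.87). All 6 genes of the phagocyte NADPH oxidase and its regulators rose (median 0.91, adjusted p = 0.00141), including RAC2 (0.99).

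Integrin genes moved in both directions, with 8 rises and 5 falls among 14, and were not called (adjusted p = 0.152; adjusted p = 0.302 with an estimated correlation). ITGB1 went from 196 to 61.3 CPM (-1.68), while the leukocyte integrin genes ITGAX and ITGB2 rose by 1.87 and 1.26. TXNIP, an inhibitor of thioredoxin, went from 245 to 696 CPM. By gene class, 32.4% of 667 long intergenic non-coding RNA genes rose and 11.4% fell (median 0.30), against 35.9% and 40.3% of 12030 protein-coding genes (median -0.03). Their median levels were 0.991 and 29.1 CPM, so the shares called are not directly comparable. Antisense genes also rose more often than they fell (27.6% and 13.7%), whereas sense intronic genes fell more often (8.39% rose, 17.4% fell). These items were also chosen after their values were seen.

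All tests in the rest of this part were chosen only after the result was seen. The rise of interferon-stimulated genes amounted to 1200 CPM in sum, from 1700 to 2899 CPM. RNA from lymphoid, erythroid, epithelial or fibroblast cells is argued against only as far as 15 abundant markers stand for those cells. These summed to 2.15 CPM in the controls and 2.77 CPM after knockdown, a difference of 0.621 CPM. They leave out PECAM1, ACTA2, KRT8 and IL7R, which rose. In the fixed lists 6 of the 7 tested epithelial and stromal markers rose, and of 7 tested lymphoid markers 3 rose and 2 fell. GC content or gene length bias is argued against as well, since the median log2 fold change of the list was 1.37 after both trends were removed and 1.35 before. Sensing of the hairpin RNA itself cannot be told apart from an effect of PRMT9 loss, because 0 libraries lacked a hairpin and the sequences and induced levels of the hairpins are not given in the sources used here. An effect of PRMT9 loss stays open as an untested hypothesis.

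Genes with the sequence GCAGGTT in the 3' UTR were lower than other genes. In a scan of 15557 7-base sequences over 11561 genes, with trends on 3' UTR length, GC content and expression removed, it had the lowest z, -5.92, against -4.36 for the next sequence and -4.76 for the lowest of 100 permutations of the genes, although genes are not independent replicates. Relative to genes without it, the mean adjusted log2 change was -0.13 (SE 0.02) for the 1002 genes that hold it. For the 118 with more than 1 copy it was -0.23 (SE 0.06). Both values come from the data in which the sequence was chosen. Its reverse complement, with the same GC content, gave 0.00191 (SE 0.0211) relative to genes without that complement. That difference cannot decide on GC content, since GCAGGTT was picked as the lowest of the scan and the reverse complement was not. The sequence occurs 2 times in the longest PRMT9 transcript, as do 18.2% of all 7-base sequences at least once, so microRNA-like pairing of the seed of a PRMT9 hairpin with other transcripts is a candidate explanation that the hairpin sequence, not given in the sources used here, would test. Direct pairing at this sequence in the 3' UTR could account for a minority of the falls, since 10.7% of 4712 fallen genes hold it. It was held by 7.11% of risen genes and by 1002 of all 11561 searched genes. The share was higher, 17.7%, among genes that fell by 2-fold or more. Unlike the z, these shares are not adjusted for 3' UTR length, so differences in length may enter them. Effects that follow from the loss of such targets stay open.

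Replication-dependent histone genes rose (median 2.01) while G1/S genes fell, although the libraries were selected for poly(A) tails, which most histone messages lack in dividing cells. More RNA without a poly(A) tail in the knockdown libraries is argued against only as far as small RNAs stand for such RNA. The 81 small RNA genes of that kind had a median log2 fold change of -0.29, with 3 rises and 18 falls. Small nucleolar RNAs, 41 of the 81, had 0 rises and 15 falls (median -0.68). They weigh on the pooled median and may have fallen for reasons of their own, as ribosome biogenesis genes also fell. GC content or gene length bias is argued against too, since the histone median was 2.06 after both trends were removed. More polyadenylated histone messages, as differentiating cells are known to make, may be behind the rise, and gene counts cannot separate these forms. Sequence shared with other genes differed between histone genes. It made up 74.1% of the 50-base windows of HIST1H2BK, against 5.36% for HIST1H2BD and 0.421% for HIST1H2AC. The rise of HIST1H2BK is therefore less certain than that of the group, and histone genes outside the named ones were not examined for this.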
